A study of Mus musculus with 6 samples.

How the data were processed

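RNA from 6 mouse hearts was measured on Clariom S mouse arrays, 1 array per heart, in 3 groups of 2: Ctrl (Tcf21iCre/Tomato) 2 and 3 months after ligation of the left coronary artery, and TTg (Tcf21iCre/Tomato/MGTH2A) at 3 months. Per the labels the mice were male and 8 weeks old, and 100 ng of RNA with an integrity number over 7.0 was labelled for each array. The deposited values were log2 values summarised per array feature by the authors. Their spread was similar across arrays, but whether they had been normalized between arrays was not tested. Transcriptome Analysis Console 4.0 is named in the submitters' processing notes, and the labels do not state the summary, background or normalization method. The highest values lie at the top of the scale, so differences between values near it may be compressed.

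All 22206 features were used without further normalization. A symbol was present for 19572 features, and 2634 had none. For 67 repeated symbols the feature with the highest mean stood for the gene in the lists. Features below the 30th percentile of mean signal (3.65) were taken as dim, where the size of a difference depends on the background. The identity of the groups came from the labels, whose series design calls the hearts independent biological replicates. Replicates are numbered in the order of the labels, and the numbers of different groups are not known to be paired.

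Differences were fitted with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 6 arrays, and spread was moderated across features (3 residual and 4.13 prior degrees of freedom). The 3 comparisons were TTg at 3 months against Ctrl at 3 months, Ctrl at 3 months against Ctrl at 2 months, and TTg at 3 months against Ctrl at 2 months. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over all features of a comparison, and the threshold was an adjusted p under 0.05. The error given is the SE of the difference from this fit, with n = 2 arrays per group. An exact permutation of 2 against 2 arrays gives no p below 0.333, so moderated tests were used.

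Gene groups were 37 lists written from general knowledge, of which 632 of 691 genes were measured and 0 genes stood in more than 1 list. They covered the 4 reprogramming factors, matrix and fibroblast states, cardiomyocyte functions and energy metabolism, vascular and immune cells, other cell types and tissues, and processes such as the cell cycle, hypoxia and the circadian clock. Each list was tested with camera in limma with the preset correlation of 0.01 between genes, adjusted over the 37 lists of a comparison. A higher or lower list means the direction of its members relative to all other features. Alternatives were camera with the correlation estimated for each list, and the rotation test fry. Counts of members adjusted over the list alone are given beside counts over all features. The matching of list genes to features was corrected after results had been seen, because 3 list genes had been matched through an older name to a feature of another gene. With the correction they count as not measured, and the lists called for TTg against Ctrl at 2 months went from 14 to 16, with glycolysis and matrix proteases added.

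Genes were named by a rule. It names the 4 factors always, and in each comparison the 10 highest and 10 lowest differences among features past the threshold with 1 symbol and a mean at or above the 30th percentile in the higher group. Where fewer passed, places were filled from features with an unadjusted p under 0.05 and groups that do not overlap. In each list it names up to 4 passing members by size or, where none passed, the 3 with the largest absolute difference, and the text uses these in rank order and may use fewer. Members that passed adjusted over the list alone are named beside them. Stard10, Jchain's values on each array, the skeletal muscle, adipocyte, platelet and Y-linked genes given per array, and the neighbouring genes on chromosome 2 were chosen after their values were seen.

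Other alternatives were an intensity trend in the prior, a robust prior, quantile normalization, median centring, leaving out dim features, features with 1 symbol, the 2 compared groups alone, a replicate block, an unadjusted p with a 2-fold minimum, and leaving out each array. With 1 array left out, the lone array of its group is assumed to vary like the other groups. The groups, comparisons, tests, lists, naming rule and these alternatives were chosen before the data were examined. The alternative with features below 19 on every array was added afterwards.

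The pipeline was tested on simulated data with the spread of these arrays. It called 2.6% of features shifted by 1 on the log2 scale, 58.6% of those shifted by 2, 96% of those shifted by 4 and all of those shifted by 8. There were 65 false and 1286 correct calls in 10 draws. Each size was given to 500 features over the draws. Many shifted features ease the adjusted threshold, so a smaller share would be called where few features change. On the real arrays, Bmp10 at 8.74 in TTg against Ctrl at 3 months had an adjusted p of 0.578 in limma. For lists of 20 features shifted by 0.5, camera with the preset correlation called 50 of 50 shifted and 2 of 320 unshifted lists when members were independent, and 49 of 50 and 121 of 320 with a within-list correlation of 0.3. With the correlation estimated, it called 0 of 50 in both cases. Figures were drawn with matplotlib 3.10.9.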

Results

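Expression was measured with mouse Clariom S arrays in heart RNA from 6 mice, 1 array per mouse, after permanent ligation of the left coronary artery. The mice formed 3 groups of 2. Control mice (Ctrl) carried Tcf21iCre and a Tomato reporter, which together mark fibroblasts of the Tcf21 lineage, and were sampled 2 or 3 months after infarction. Transgenic mice (TTg) also carried MGTH2A, a transgene for the cardiac transcription factors Mef2c, Gata4, Tbx5 and Hand2, and were sampled at 3 months. The table held 22206 array features, of which 19572 had 1 gene symbol. On the log2 scale, 35 to 41 features per array lay at or above 19, close to the top of the range. Replicates correlated across features at 0.984 for Ctrl at 2 months, 0.986 for Ctrl at 3 months and 0.989 for TTg at 3 months. They differed by at least 2-fold in 7.66%, 6.47% and 3.97% of features. With 2 arrays per group, the number of arrays limits the precision of every value below. Differences are log2 differences of group means ± SE from the limma fit, with n = 2 arrays in each group. For single genes, limma's p-values set the difference against the spread between independent hearts. For lists, camera's p-values with the preset correlation compare the members with all other features. They assume a correlation of 0.01 between genes and do not measure how a list's mean varies between hearts.

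The comparison of TTg with Ctrl at 3 months asks what the transgene changed in the chronically infarcted heart. In TTg hearts, lists of fibrillar collagen, extracellular matrix, activated fibroblast, late scar fibroblast and macrophage genes were lower as groups. So were immediate early genes and fetal and stress genes of cardiomyocytes. Lists of calcium handling, fatty acid oxidation and oxidative phosphorylation genes were higher as groups, as were the 4 transgene factors together. These calls are camera's with the preset correlation, and 0 of the 37 lists passed with an estimated correlation (smallest adjusted p = 0.382). The calcium handling, fatty acid oxidation and oxidative phosphorylation calls also ended without Ctrl 3-month replicate 1, at means of 0.19, 0.08 and 0.11, and the fatty acid oxidation call ended without TTg replicate 2, at 0.18. Jchain, the joining chain of secreted antibodies, was the 1 gene that passed limma's test by itself and fell by 4.06 on the log2 scale (SE 0.27, n = 2, 16.6-fold lower, adjusted p = 0.0278). Its values were 4.75 and 5.08 in TTg and 9.07 and 8.87 in Ctrl. The call for Jchain ended when any TTg or Ctrl 3-month array was left out, as given below.

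Of the 4 factors, Tbx5 had a difference of 3.07 ± 0.52 (n = 2), an 8.40-fold higher mean of 10.02 against 6.95. Mef2c differed by 2.24 ± 0.58, Hand2 by 0.98 ± 0.44 and Gata4 by 0.26 ± 0.31. None of the 4 passed over all features, with an adjusted p of 0.646 for Tbx5 and 0.650 for Mef2c. Adjusted over the list alone, 2 of the 4 passed, Tbx5 at an adjusted p of 0.00213 and Mef2c at 0.0117. The array features do not separate the transgene's transcripts from those of the endogenous genes. TTg replicate 1 had the higher value of the pair for all 4 genes, 15.93 against 13.94 for Mef2c. As a group the 4 genes were higher by a mean of 1.64 (camera, adjusted p = 1.69e-04 with the preset correlation, adjusted p = 0.382 with an estimated correlation). Without TTg replicate 1 their mean was 0.97, and the group still passed. Gata4 was at −0.06 without that array and at −0.01 without Ctrl 3-month replicate 1.

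**Figure D1:**
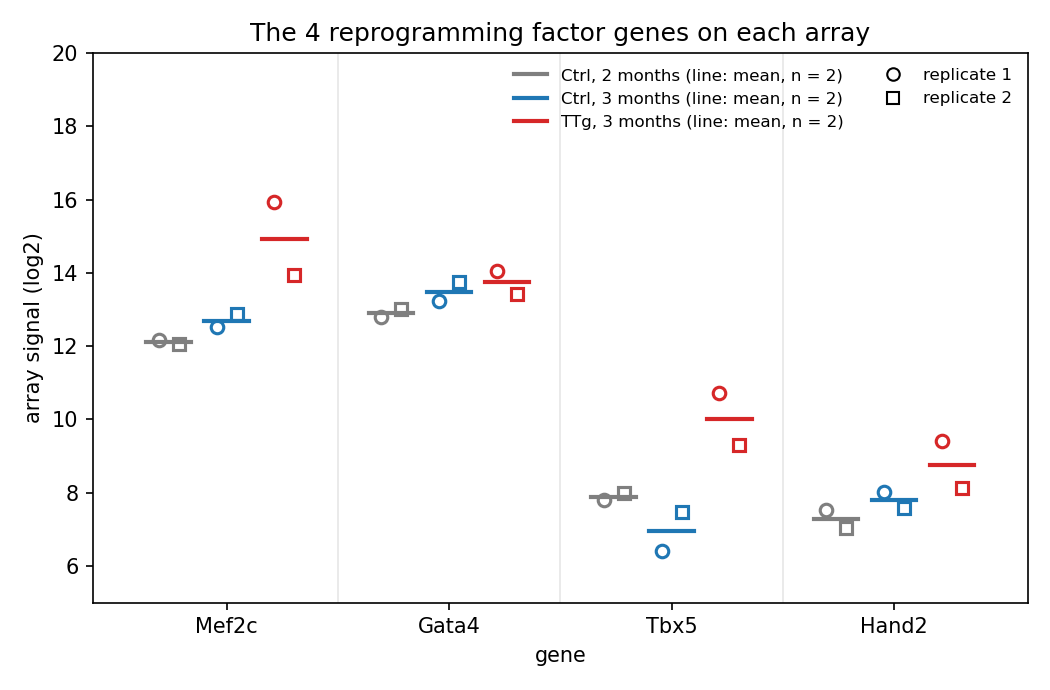
Array signal (log2, vertical axis) of Mef2c, Gata4, Tbx5 and Hand2 on each of the 6 arrays, with circles for replicate 1, squares for replicate 2 and lines for group means (n = 2). Tbx5 lay at 10.72 and 9.31 in TTg and between 6.42 and 7.98 in Ctrl, while the Gata4 values of the 3-month groups overlapped.

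Matrix and fibroblast lists were lower in TTg. Of 17 measured genes for fibrillar collagens and their crosslinking, 14 were lower and 3 higher (mean −1.02, adjusted p = 2.72e-06). The largest differences were those of the crosslinking enzymes Lox (−2.83 ± 0.52), Loxl3 (−2.24 ± 0.64) and Loxl1 (−2.04 ± 0.64). Among 25 other matrix genes, 22 were lower (mean −1.28, adjusted p = 3.25e-13), led by Thbs1 (−3.30 ± 0.61), Mfap4 (−3.14 ± 1.27) and Mfap5 (−2.41 ± 0.71). Activated fibroblast and myofibroblast genes were lower in 17 of 20 (mean −1.37, adjusted p = 6.86e-08). Fmod differed by −3.66 ± 1.21, Postn, a matrix protein of healing scars, by −3.09 ± 1.09 and Meox1 by −3.09 ± 0.89. Genes of late scar fibroblasts were lower in 13 of 14 (mean −1.91, adjusted p = 4.71e-07), with Comp at −4.89 ± 1.39, Sfrp2 at −3.88 ± 1.46 and Ccn5 at −3.46 ± 0.81. Resting fibroblast genes were lower in 15 of 17 (mean −0.74, adjusted p = 1.33e-05), with Tcf21, the gene whose promoter drives the Cre, at −1.86 ± 1.0 and Igfbp4 at −1.31 ± 0.84. TGF-beta pathway genes were lower in 14 of 17 (mean −0.62, adjusted p = 3.50e-04), with Tgfb2 at −2.25 ± 0.56. Matrix proteases and their inhibitors were lower in 18 of 19 (mean −0.93, adjusted p = 1.74e-07), with Mmp3 at −2.69 ± 0.50. Each of these 7 lists had an adjusted p = 0.382 with an estimated correlation. No member passed limma's test over all features. Adjusted over the list alone, 4 fibrillar collagen and crosslinking genes, 4 other matrix genes, 3 late scar genes and 1 protease gene passed, all lower, and none in the activated, resting and TGF-beta lists. Without Ctrl 3-month replicate 1 the means were −0.66, −0.84, −0.85, −1.06, −0.50 and −0.37 for the fibrillar, other matrix, activated, late scar, resting and TGF-beta lists, all still past the threshold.

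Replicate 1 had the higher mean of its pair for the fibroblast and macrophage lists in every group. The late scar list, for instance, had array means of 9.73 and 8.02 in Ctrl at 3 months and 7.53 and 6.40 in TTg. Endothelial genes, a marker group of another cell type of the heart, had a mean difference of −0.22 (adjusted p = 0.192), and mural cell genes one of 0.05 (adjusted p = 0.979). The endothelial list passed without Ctrl 3-month replicate 2, at −0.46.

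**Figure D2:**
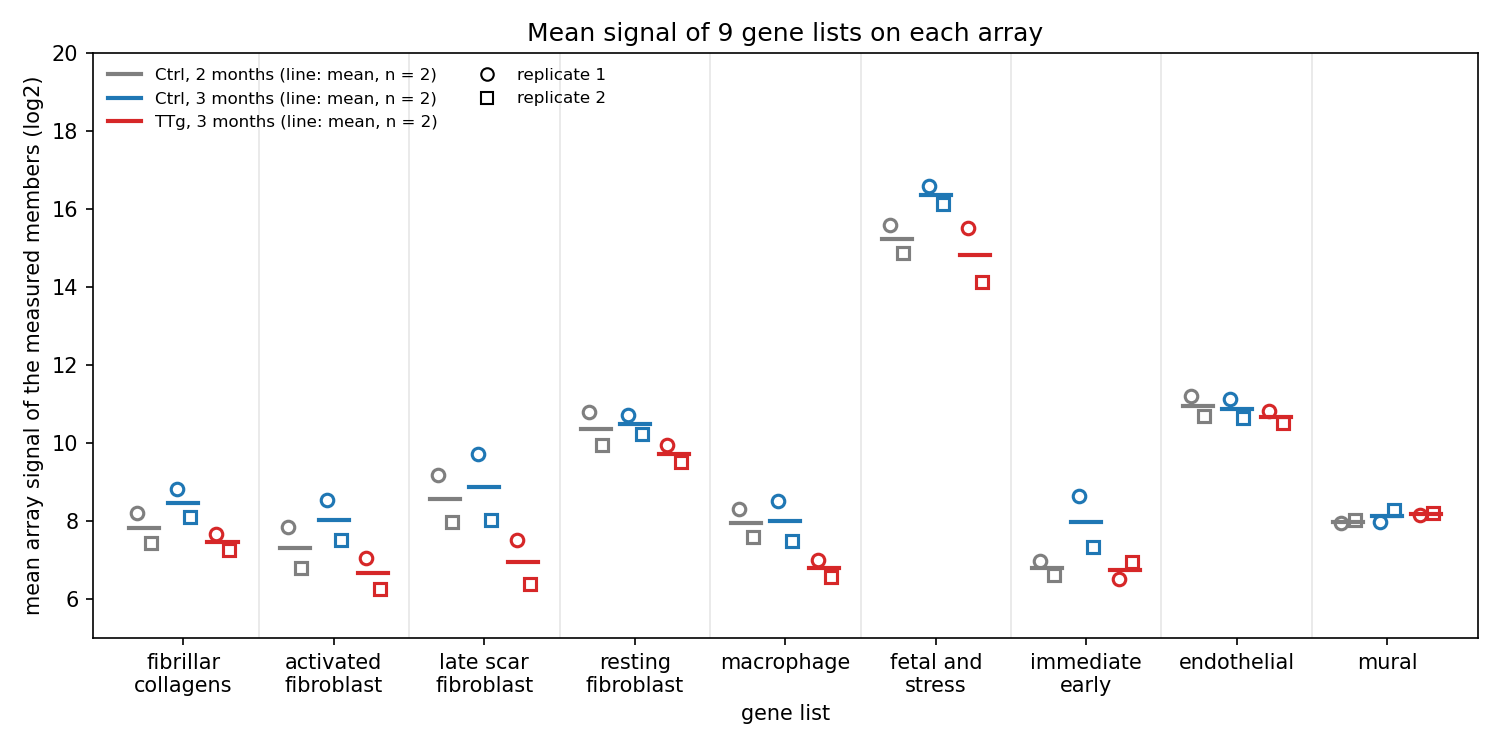
Mean array signal (log2, vertical axis) of the measured members of 9 gene lists on each array, with circles for replicate 1, squares for replicate 2 and lines for group means (n = 2). Activated fibroblast means were 7.05 and 6.27 in TTg and 8.55 and 7.51 in Ctrl at 3 months, whereas mural cell means stayed between 7.95 and 8.28 in all 6 arrays.

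Immune and inflammatory lists were also lower in TTg. All 24 macrophage and monocyte genes had a lower mean (group mean −1.21, adjusted p = 1.64e-12), including Ctss (−2.41 ± 0.69), the complement gene C1qb (−2.10 ± 0.64) and Lyz2 (−2.06 ± 0.61). Of 27 cytokine and chemokine genes, 26 were lower (mean −0.73, adjusted p = 1.74e-07), with Ccl9 at −2.67 ± 0.51 and Ccl8 at −2.01 ± 0.62. The B and plasma cell list was lower in 9 of 13 (mean −0.45, median −0.28, adjusted p = 0.0268), and Jchain passed in it both over all features and adjusted over the list alone. No other member had an unadjusted p under 0.05 in limma, so much of this mean comes from Jchain. These 3 lists had an adjusted p = 0.382 with an estimated correlation. Antigen presentation genes were lower in 14 of 14 (mean −1.03, adjusted p = 1.81e-05), with the class II genes H2-Aa at −2.23 ± 0.80 and H2-DMb1 at −2.18 ± 0.77. Interferon response genes were lower in 18 of 22 (mean −0.42, adjusted p = 2.86e-04), with Ifit2 at −1.21 ± 0.33. The latter 2 lists had an adjusted p = 0.419 with an estimated correlation. Adjusted over the list alone, Ccl9 and Ccl3 passed, and no gene of the macrophage, antigen presentation or interferon lists did. Leaving out Ctrl 3-month replicate 1 moved the macrophage mean to −0.70 and the cytokine mean to −0.37, both still past the threshold. The same array ended the calls of antigen presentation (−0.41), interferon (−0.20) and B and plasma cells (−0.42), whereas without Ctrl 3-month replicate 2 the antigen presentation mean was −1.65 and the interferon mean −0.65. The B and plasma cell call also ended without Ctrl 3-month replicate 2 (−0.47) and without TTg replicate 2 (−0.35). T and NK cell genes (−0.17, adjusted p = 0.105) and neutrophil and mast cell genes (0.19, adjusted p = 0.158) did not pass, though the former did without TTg replicate 1 (−0.24) and the latter without Ctrl 3-month replicate 1 (0.30).

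Among cardiomyocyte genes, 14 of 15 fetal and stress genes were lower in TTg and none was higher (mean −1.54, adjusted p = 4.08e-09). Skeletal actin Acta1 differed by −4.19 ± 1.13 (n = 2), Rcan1 by −2.85 ± 1.10 and Mt2 by −2.50 ± 1.17, and Xirp2 passed adjusted over the list alone (−2.21 ± 0.50). On some array 6 of the 15 genes, Acta1 among them, reached 19 or more, close to the top of the scale, where differences can be compressed. With features below 19 on every array alone, an alternative chosen after seeing the data, the mean was −1.62 and still passed. Without TTg replicate 2 this list's mean was −0.85, still past the threshold. All 20 immediate early genes, which respond within minutes to stimuli, were lower (mean −1.25, adjusted p = 3.09e-09), led by Nr4a3 (−3.53 ± 1.53), Atf3 (−2.75 ± 0.76) and Nr4a1 (−2.48 ± 0.49), the last of which passed adjusted over the list alone. Their mean was −0.61 without Ctrl 3-month replicate 1 and −1.90 without Ctrl 3-month replicate 2. Array means of the immediate early list were 8.64 and 7.35 in Ctrl at 3 months and 6.52 and 6.95 in TTg. In Ctrl at 2 months they were 6.97 and 6.63, near those of TTg. These 2 lists had an adjusted p = 0.382 with an estimated correlation.

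Calcium handling and excitation genes were higher in 18 of 20 (mean 0.55, adjusted p = 1.45e-04), led by the potassium channel genes Kcnj2 (2.25 ± 0.52) and Kcnh2 (1.39 ± 0.53). Fatty acid oxidation genes were higher in 20 of 23 (mean 0.49, adjusted p = 3.41e-05), with Slc25a20 at 1.29 ± 0.56 and Acot2 at 1.11 ± 0.47. Oxidative phosphorylation and TCA cycle genes were higher in 26 of 30 (mean 0.32, adjusted p = 5.13e-05), with Sdha at 0.92 ± 0.37. Each of these 3 lists had an adjusted p = 0.419 with an estimated correlation, and no member passed adjusted over the list alone. All 3 calls ended without Ctrl 3-month replicate 1, at means of 0.19, 0.08 and 0.11, and without Ctrl 3-month replicate 2 the means were 0.91, 0.90 and 0.52. Fatty acid oxidation was at 0.80 without TTg replicate 1 and lost its call at 0.18 without TTg replicate 2. Sarcomere genes had a mean of −0.01, a median of 0.03 and a camera direction of lower (adjusted p = 0.981), with Nrap at −0.98 ± 0.26. Glycolysis genes had a mean of −0.00469, a median of 0.03 and a camera direction of higher (adjusted p = 0.772).

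Some atrial genes differed widely, whereas the atrial and conduction list as a whole had a median of 0.21. Bmp10, a growth factor of atrial myocytes, had a mean of 11.69 in TTg and 2.96 in Ctrl, a difference of 8.74 ± 1.21 (n = 2), but did not pass over all features (adjusted p = 0.578, range 0.000987 to 0.999 over the alternatives). Its Ctrl values at 3 months, 2.87 and 3.04, lie below the 30th percentile of all features (3.65), so the size of the difference depends on the background. It passed without either Ctrl 2-month array and with the 2 groups alone, where the distance between the Ctrl 2-month arrays, at 2.40 and 6.88, does not enter the pooled spread. Myl7, the atrial myosin light chain, differed by 4.99 ± 1.83 and Myl4 by 4.39 ± 2.75. Both rested on Ctrl 3-month replicate 2, whose values were 3.45 for Myl7, 5.90 for Myl4 and 5.53 for Sln. The same 3 genes were at 10.21, 16.08 and 13.78 in Ctrl 3-month replicate 1. Without Ctrl 3-month replicate 2, Myl7 differed by 1.61, and without Ctrl 3-month replicate 1 it differed by 8.37 and passed. Of the 15 measured list members, 10 were higher (mean 1.53, adjusted p = 0.00859, adjusted p = 0.408 with an estimated correlation), and Bmp10 and Stard10 (1.68), the latter named after its values were seen, passed adjusted over the list alone. The list's call ended without Ctrl 3-month replicate 2, at 0.46, and without TTg replicate 1, at 1.22, and its mean was 2.61 without Ctrl 3-month replicate 1.

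**Figure D3:**
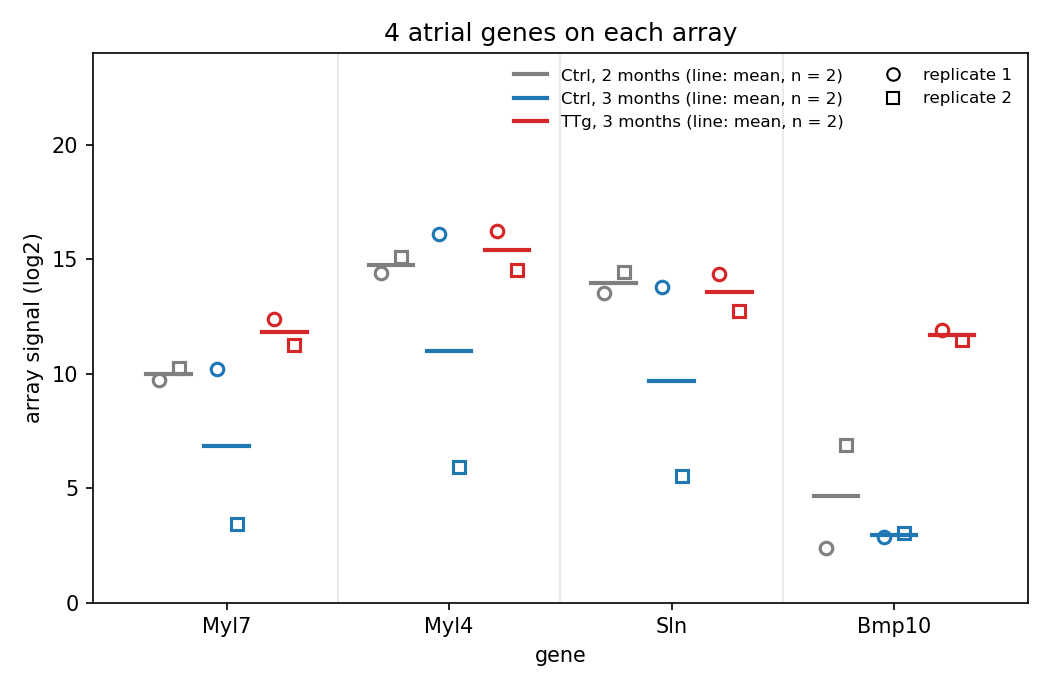
Array signal (log2, vertical axis) of the atrial genes Myl7, Myl4, Sln and Bmp10 on each array, with circles for replicate 1, squares for replicate 2 and lines for group means (n = 2). Bmp10 lay at 11.92 and 11.46 in TTg and at or below 6.88 in the 4 Ctrl arrays, and Myl7, Myl4 and Sln were low in Ctrl 3-month replicate 2 alone, at 3.45, 5.90 and 5.53.

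Cell cycle genes were lower in 21 of 26 (mean −0.33, adjusted p = 0.00167), with Ccna2 at −1.11 ± 0.51. Epicardial and mesothelial genes were lower in 11 of 13 (mean −0.50, adjusted p = 0.00405), with Msln at −1.07 ± 0.48. Both lists had an adjusted p = 0.419 with an estimated correlation. Both calls ended without Ctrl 3-month replicate 1, at −0.05 and −0.03, and without Ctrl 3-month replicate 2 the means were −0.62 and −0.98. Natriuretic, neurohormonal and fibrosis regulators had a mean of −0.54 (adjusted p = 0.0594), with the Wnt modulator Sfrp1 at −3.45 ± 0.87. This list passed in 9 of the 13 alternatives that kept the preset correlation, among them without Ctrl 3-month replicate 2, at −0.87, and its means ran up to −0.22 over the arrays left out. Genes of hypoxia and the unfolded protein response had a mean of −0.25 (adjusted p = 0.0600) and passed without TTg replicate 2, at −0.33. The remaining lists did not pass with all arrays. Their means were −0.23 for the circadian clock (adjusted p = 0.640), −0.12 for Schwann cells and neurons (0.30), −0.11 for lung and thymus (0.640) and 0.04 for skeletal muscle (0.912). For erythroid cells and platelets the mean was 0.59 (0.272), with Ppbp at 10.70 in TTg replicate 2 and at or below 7.13 elsewhere. Without TTg replicate 1 that list passed at 1.35, and the circadian list passed in opposite directions, at 0.46 without TTg replicate 1 and −0.91 without TTg replicate 2. For adipocytes the mean was −0.02, with a median of 0.03 and a camera direction of higher (0.806). For cartilage and bone the mean was −0.03, with a camera direction of higher (0.979). The 3 measured Y-linked genes had a mean of 0.12 (0.979).

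Other named genes with the highest differences, none of which passed, were Lrrc4b (2.70 ± 0.63), Lgals4 (2.38 ± 0.46), the iron hormone Hamp (2.24 ± 0.57), Ubxn10 (2.23 ± 0.50) and the vessel growth factor Angpt1 (2.17 ± 0.48). Those with the lowest were Resf1 (−3.75 ± 0.51), Serpina3n (−3.66 ± 1.22) and the histone gene H2ac15 (−3.45 ± 0.94). Their adjusted p lay between 0.578 and 0.661.

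In limma, 1 of 22206 features passed at an adjusted p under 0.05, lower in TTg. At an unadjusted p under 0.05 there were 1658, 745 higher and 913 lower, where 1110.3 are expected by chance, and 666 of these also differed by at least 2-fold, 222 higher and 444 lower. Jchain kept its direction in all 15 alternatives (−4.22 to −3.89) and its call in 11, and it lost the call without either Ctrl 3-month array or either TTg array (adjusted p 0.00944 to 0.254 over the alternatives). The values of the 2 groups did not overlap for 38.38% of features, against a chance share of 33.33%. Of the 37 lists, 21 passed camera with the preset correlation, 5 higher and 16 lower, and 14 passed without Ctrl 3-month replicate 1. With an estimated correlation 0 lists passed, and 0 passed fry's test for a change in 1 direction, whose smallest adjusted p was 0.341. Its test for changes in either direction passed 2 lists, the atrial and the B and plasma cell genes (adjusted p = 0.0133 for both). Estimated correlations of the 21 lists ran from 0.0594 to 0.752. On simulated data with a within-list correlation of 0.3, the preset test also called 37.8% of lists with no shift, so the preset calls may be too many. The test with an estimated correlation called 0 of 50 lists shifted by 0.5. Larger shifts, such as the late scar mean of −1.91, and correlations above 0.3 were not simulated. The draws therefore do not show how either test performs at the values seen here.

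**Figure D4:**
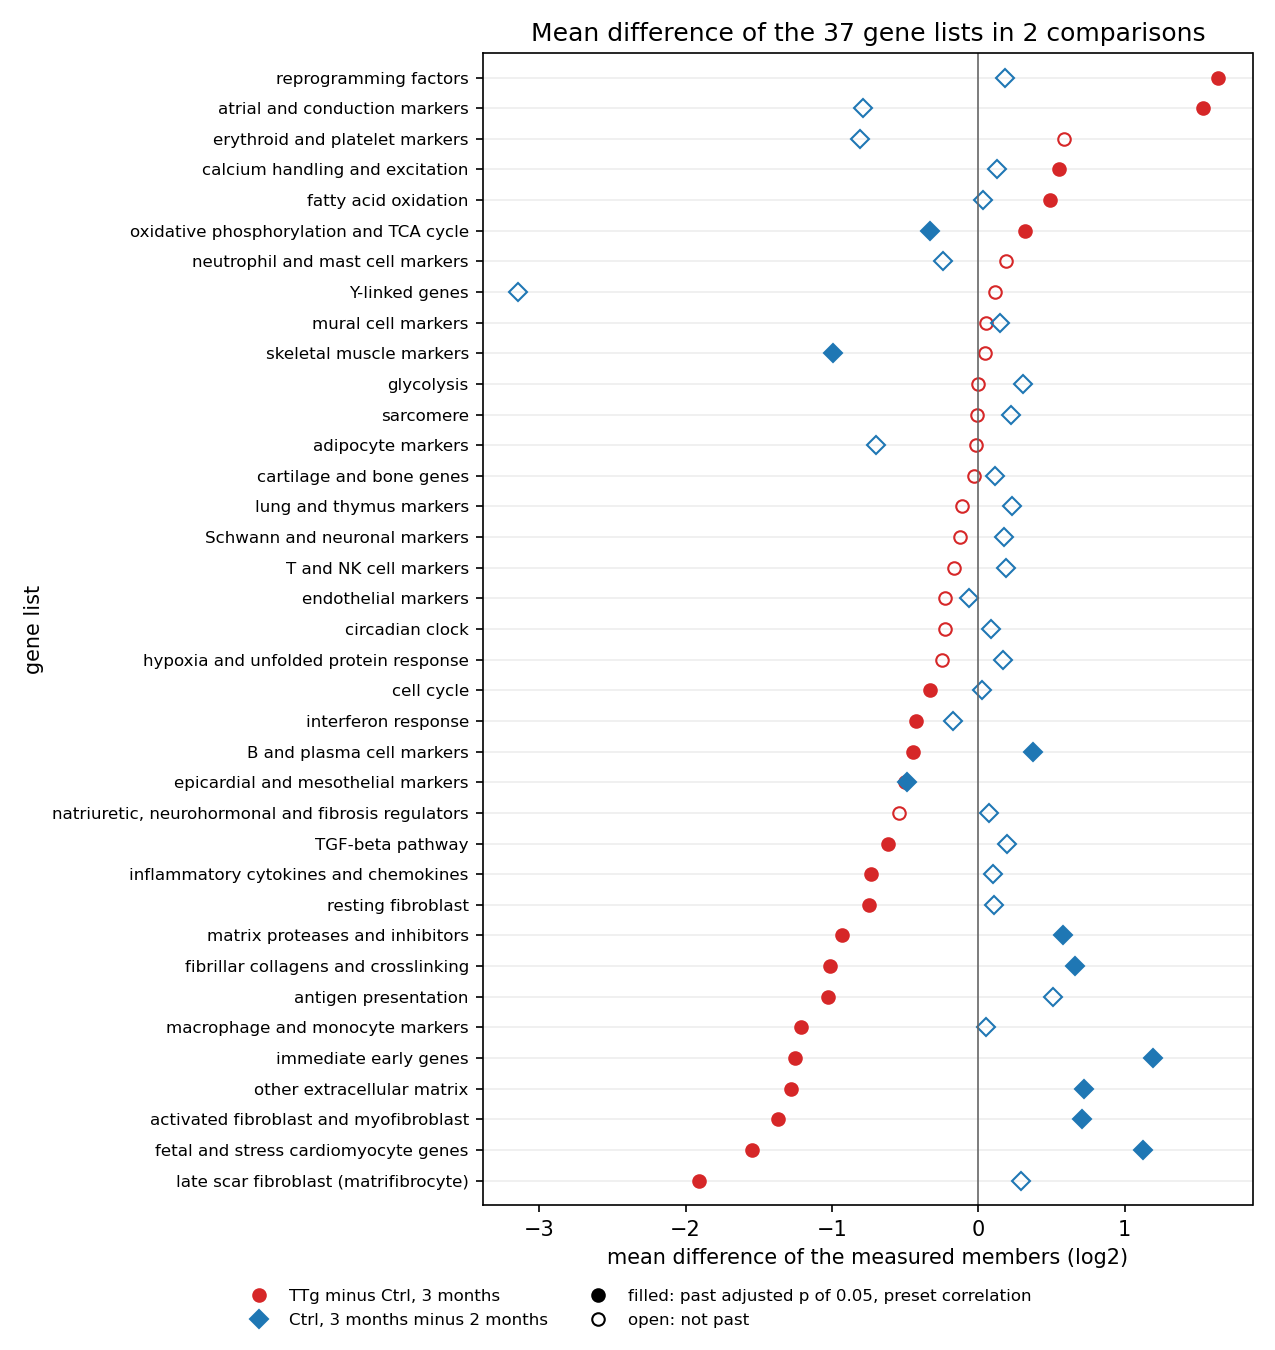
Mean log2 difference (horizontal axis) of the measured members of each of the 37 gene lists, with circles for TTg against Ctrl at 3 months and diamonds for Ctrl at 3 against 2 months, filled where camera passed with the preset correlation. The late scar list lies lowest for TTg against Ctrl at −1.91, and 8 lists are filled on opposite sides of 0 in the 2 comparisons.

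The comparison of Ctrl at 3 months with Ctrl at 2 months asks how the infarcted heart without the transgene changed over the intervening month. Lists of immediate early, fetal and stress, matrix and activated fibroblast genes were higher at 3 months as groups, and oxidative phosphorylation genes were lower. With an estimated correlation 0 of the 37 lists passed camera (smallest adjusted p = 0.634). Without Ctrl 2-month replicate 2 the fetal and stress (0.77), fibrillar collagen (0.28), other matrix (0.29) and activated fibroblast (0.19) calls ended. Without Ctrl 3-month replicate 1 the other matrix (0.28), activated fibroblast (0.19) and oxidative phosphorylation (−0.12) calls did. Adh1, an alcohol dehydrogenase of resting fibroblasts that also oxidises retinol, was the 1 gene that passed limma's test and fell by 3.57 on the log2 scale (SE 0.26, n = 2, 11.8-fold lower, adjusted p = 0.0457). Its values were 8.14 on both arrays at 3 months and 11.48 and 11.93 at 2 months. The call for Adh1 ended in most of the alternatives, as given below.

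Of the 20 immediate early genes 18 were higher at 3 months (mean 1.19, adjusted p = 2.56e-05, adjusted p = 0.634 with an estimated correlation). Nr4a3 differed by 5.46 ± 1.53 (n = 2), Nr4a1 by 3.98 ± 0.49 and Atf3 by 2.25 ± 0.76, and Nr4a1 passed adjusted over the list alone. Fetal and stress genes were higher in 13 of 15 (mean 1.13, adjusted p = 1.03e-04, adjusted p = 0.634 with an estimated correlation), with the calcineurin regulator Rcan1 at 3.94 ± 1.10, Ankrd23 at 2.80 ± 0.64 and Acta1 at 2.39 ± 1.13, both of which reached 19 on 1 array at 3 months. With features below 19 on every array alone the mean was 1.22 and passed, and sarcomere genes, 6 of which reached 19, then passed at 0.31. Adjusted over the list alone 4 of the fetal and stress genes passed, all higher. The immediate early mean was 0.55 without Ctrl 3-month replicate 1 and 1.84 without Ctrl 3-month replicate 2, and the fetal and stress call ended without Ctrl 2-month replicate 2, at 0.77. Oxidative phosphorylation and TCA cycle genes were lower in 25 of 30 (mean −0.33, adjusted p = 1.03e-04, adjusted p = 0.634 with an estimated correlation), with Cox8b at −1.0 ± 0.31 and Sdhd at −0.89 ± 0.28. That call ended without Ctrl 3-month replicate 1, at −0.12, and the mean was −0.53 without Ctrl 3-month replicate 2. Sarcomere genes did not pass as a group (0.22, adjusted p = 0.126), while Nrap (1.90 ± 0.26) passed adjusted over the list alone. The other cardiomyocyte lists did not pass either, with means of 0.13 for calcium handling, 0.31 for glycolysis and 0.03 for fatty acid oxidation, whose median was −0.09 and camera direction lower. Fatty acid oxidation passed in opposite directions, at 0.44 without Ctrl 3-month replicate 1 and −0.38 without Ctrl 3-month replicate 2. Sarcomere genes passed without Ctrl 2-month replicate 2 (0.35) or Ctrl 3-month replicate 1 (0.36), as did calcium handling (0.44 and 0.49), and glycolysis passed in 8 of the 13 alternatives that kept the preset correlation.

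Fibrillar collagen and crosslinking genes were higher at 3 months in 15 of 17 (mean 0.66, adjusted p = 1.16e-04), with Loxl3 at 1.58 ± 0.64, Lox at 1.54 ± 0.52 and Col1a1 at 1.42 ± 0.57. Other matrix genes were higher in 21 of 25 (mean 0.72, adjusted p = 1.03e-04). Adjusted over the list alone 4 of these passed, led by Thbs1 (3.54 ± 0.61), Vcan (2.21 ± 0.36) and Col15a1 (1.70 ± 0.37). Activated fibroblast genes were higher in 17 of 20 (mean 0.71, adjusted p = 0.00328), with Meox1 at 2.59 ± 0.89 and Tgfb1i1 at 1.76 ± 0.43. Proteases and inhibitors were higher in 14 of 19 (mean 0.58, adjusted p = 0.0128), with the macrophage elastase gene Mmp12 at 4.77 ± 1.59. These 4 lists had an adjusted p = 0.634 with an estimated correlation. Without Ctrl 2-month replicate 2 all 4 calls ended, at means of 0.28, 0.29, 0.19 and 0.42. Without Ctrl 3-month replicate 1 the fibrillar list stayed past the threshold at 0.30, and the other 3 lost their calls at 0.28, 0.19 and 0.31. Without Ctrl 2-month replicate 1 the fibrillar, other matrix and activated means were 1.04, 1.15 and 1.23, and without Ctrl 3-month replicate 2 they were 1.02, 1.16 and 1.23. Late scar (0.29), resting fibroblast (0.11) and TGF-beta genes (0.20) did not pass, with adjusted p of 0.529, 0.379 and 0.425. All 3 passed without Ctrl 2-month replicate 1, at 0.89, 0.53 and 0.46, and late scar also without Ctrl 3-month replicate 2, at 1.15. The protease call ended, at 0.53, when only features at or above the 30th percentile were used. Within the resting list, Clec3b (−1.99 ± 0.51), Col4a2 (1.57 ± 0.32) and Col4a1 (1.19 ± 0.31) passed adjusted over the list alone.

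B and plasma cell genes were higher in 10 of 13 (mean 0.37, adjusted p = 0.0126), with Jchain at 2.04 ± 0.27, which passed adjusted over the list alone. Epicardial and mesothelial genes were lower in 11 of 13 (mean −0.49, adjusted p = 0.0186), with Gpm6a at −1.69 ± 0.48. Both lists had an adjusted p = 0.634 with an estimated correlation. The B and plasma cell call ended without Ctrl 2-month replicate 2, at 0.24, and with features at or above the 30th percentile alone, at 0.39. The epicardial call ended without that array (−0.34) and without Ctrl 3-month replicate 2 (−0.01), and its mean was −0.97 without Ctrl 3-month replicate 1. Skeletal muscle genes were lower in 14 of 15 (mean −0.99, adjusted p = 0.00328, adjusted p = 0.658 with an estimated correlation), and this rested on Ctrl 2-month replicate 1. That array had values of 10.51 for Myh2 and 8.47 for Mylpf, against 3.31 to 3.81 and 2.77 to 3.95 elsewhere, and without it the mean was 0.12, not past the threshold. It also stood apart in the adipocyte list (mean −0.70, adjusted p = 0.108), with Adipoq at 10.34 against 3.98 to 4.83, and that list passed without Ctrl 2-month replicate 2 (−1.43) or Ctrl 3-month replicate 2 (−0.97). Without Ctrl 2-month replicate 2 the skeletal muscle mean was −2.10.

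Of the 3 measured Y-linked genes, Eif2s3y had values of 10.86 in Ctrl 2-month replicate 2 and 2.48 to 2.90 on the other 5 arrays, and Uty of 10.61 and 2.49 to 2.91. Their list had a mean of −3.14 (adjusted p = 0.0534), and passed in 6 of the 12 alternatives that kept the preset correlation, among them without Ctrl 2-month replicate 1, at −6.44. Lists without a call included antigen presentation (0.51, adjusted p = 0.0526), erythroid cells and platelets (−0.81, adjusted p = 0.0505), cytokines (0.10), interferon response (−0.17), T and NK cells (0.19), neutrophils and mast cells (−0.24), endothelial (−0.06) and mural cells (0.15). Antigen presentation passed in 10 of the 13 alternatives that kept the preset correlation, with means from −0.12 to 1.13 over the arrays left out (1.07 without Ctrl 2-month replicate 1), and erythroid cells and platelets in 8 of 13. Cytokines passed without Ctrl 2-month replicate 1 (0.33) or Ctrl 3-month replicate 2 (0.46), and the interferon response without Ctrl 2-month replicate 2 (−0.43) or Ctrl 3-month replicate 1 (−0.40). Macrophage genes had a mean of 0.05, a median of −0.13 and a camera direction of lower (adjusted p = 0.859). The atrial list had a mean of −0.79 and a median of 0.01 (adjusted p = 0.461), the circadian list a mean of 0.09 and a median of −0.36, and the neurohormonal list a mean of 0.07 and a median of −0.04. Cell cycle genes had a mean of 0.03 with a camera direction of lower. Without Ctrl 3-month replicate 1 the macrophage (−0.46), cell cycle (−0.26) and atrial (−1.87) lists passed, and without Ctrl 3-month replicate 2 the macrophage (0.56) and cell cycle (0.31) lists passed in the other direction.

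Other named genes with the highest differences, none past the threshold, were the cell cycle inhibitor Cdkn1a (4.01 ± 0.63), Irs2 (3.22 ± 0.67), Sik1 (3.09 ± 0.75), Synpo2l (3.01 ± 0.63) and Xirp1 (2.86 ± 0.67). Those with the lowest were Baiap2l1 (−5.23 ± 1.33), Gsta3 (−3.21 ± 0.56), the RNA gene Rmrp (−2.90 ± 0.69), Fmo2 (−2.68 ± 0.41) and Pkhd1l1 (−2.58 ± 0.65). The 4 factors differed by 0.58 for Mef2c, 0.59 for Gata4, −0.94 for Tbx5 and 0.51 for Hand2, without a call alone or as a list (mean 0.18, adjusted p = 0.488).

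In limma, 1 feature passed, lower at 3 months, against 1776 at an unadjusted p under 0.05, 868 higher and 908 lower. Adh1 kept its direction in all 15 alternatives and its call in 5 (adjusted p 0.0179 to 0.212), and it lost the call when any of the 6 arrays was left out, with differences between −3.79 and −3.34. The features past the threshold changed with the array left out. Without Ctrl 2-month replicate 1 they were Y-linked, among them Eif2s3y (−8.29) and Uty (−7.84). Without Ctrl 2-month replicate 2 they included skeletal muscle and adipocyte genes, such as Myh2 (−6.95) and Adipoq (−5.88). These differences follow the values of the 1 Ctrl 2-month array left in, so they are not read as changes over time. Groups did not overlap for 35.67% of features, against 33.33% by chance. Of the 37 lists 10 passed with the preset correlation, 7 higher and 3 lower, and 16 did without Ctrl 2-month replicate 1 or Ctrl 3-month replicate 2. With an estimated correlation or with fry's test for a change in 1 direction, 0 lists passed. Fry's test for changes in either direction passed 5, with adjusted p of 1.09e-04 for mural cells, 0.0112 for B and plasma cells, 0.0160 for atrial genes, 0.0345 for cartilage and bone and 0.0462 for T and NK cells.

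The comparison of TTg at 3 months with Ctrl at 2 months sets the transgenic hearts against the earlier state of the control hearts, and it mixes genotype and time. Macrophage, late scar, epicardial and interferon genes were lower in TTg as groups, and the 4 factors and calcium handling genes were higher. With an estimated correlation 0 of the 37 lists passed camera (adjusted p = 0.631 for each of these). No gene passed limma's test. The smallest adjusted p was 0.0762, for Adh1 (−3.31 ± 0.26, n = 2), and Bmp10 had the highest difference at 7.05 ± 1.21.

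Macrophage and monocyte genes were lower in 22 of 24 (mean −1.16, adjusted p = 4.48e-10), and C1qb (−2.49 ± 0.64), Folr2 (−2.29 ± 0.59) and 2 others passed adjusted over the list alone. Interferon response genes were lower in 19 of 22 (mean −0.60, adjusted p = 4.63e-05), with Ifit2 (−1.61 ± 0.33) and Rtp4 (−1.48 ± 0.31) passing adjusted over the list alone. Cytokine genes were lower in 19 of 27 (mean −0.64, adjusted p = 0.00202), with Vcam1 at −2.54 ± 0.90 and Ccl12 at −2.38 ± 0.85. Late scar genes were lower in 13 of 14 (mean −1.62, adjusted p = 1.19e-04), and Angptl7 (−5.11 ± 1.10) and Ccn5 (−3.66 ± 0.81) passed adjusted over the list alone. These 4 lists had an adjusted p = 0.631 with an estimated correlation. Without Ctrl 2-month replicate 1 the late scar mean was −1.02 and the interferon mean −0.34, both still past the threshold, and the cytokine call ended at −0.40. The late scar mean was −1.05 without TTg replicate 2.

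Other matrix genes were lower in 17 of 25 (mean −0.56, adjusted p = 0.00562), with Mfap4 at −2.05 ± 1.27. Activated fibroblast genes were lower in 16 of 20 (mean −0.66, adjusted p = 0.0213), with Fmod at −2.89 ± 1.21, Postn at −2.27 ± 1.09 and, in the other direction, smooth muscle actin Acta2 at 2.23 ± 0.59. Resting fibroblast genes were lower in 12 of 17 (mean −0.64, adjusted p = 0.00686), with Tcf21 at −1.63 ± 1.0. TGF-beta genes were lower in 14 of 17 (mean −0.42, adjusted p = 0.0193), and Tgfbi (−1.77 ± 0.39) passed adjusted over the list alone. Proteases were lower in 12 of 19 (mean −0.36, adjusted p = 0.0491), although Mmp12 was at 3.94 ± 1.59. These 5 lists had an adjusted p = 0.631 with an estimated correlation. All 5 calls ended without Ctrl 2-month replicate 1, at −0.13, −0.14, −0.21, −0.16 and −0.21, and without TTg replicate 2, at −0.30, −0.27, −0.42, −0.27 and −0.30. Without Ctrl 2-month replicate 2 the first 4 means were −0.99, −1.18, −1.06 and −0.68, and the activated mean was −1.05 without TTg replicate 1. The activated call also ended with features at or above the 30th percentile alone, at −0.64. Fibrillar collagens (−0.36, adjusted p = 0.414) and fetal and stress genes (−0.42, adjusted p = 0.257) did not pass. The former passed without Ctrl 2-month replicate 2 (−0.74) and the latter without TTg replicate 1 (−1.11).

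Calcium handling genes were higher in 16 of 20 (mean 0.67, adjusted p = 1.03e-04), led by Kcnd2 (1.74 ± 0.51) and the calcium release channel gene Ryr2 (1.57 ± 0.45). Fatty acid oxidation genes were higher in 20 of 23 (mean 0.52, adjusted p = 0.00202), with Ppara at 1.63 ± 0.66, and glycolysis genes in 11 of 16 (mean 0.30, adjusted p = 0.0288), with Hk2 at 1.05 ± 0.42. The 4 factors were higher by a mean of 1.82 (adjusted p = 8.39e-05), and all 4 passed adjusted over the list alone, Mef2c at 2.82 ± 0.58, Tbx5 at 2.13 ± 0.52, Hand2 at 1.49 ± 0.44 and Gata4 at 0.84 ± 0.31. These 4 lists had an adjusted p = 0.631 with an estimated correlation. The calcium mean was 0.36 without Ctrl 2-month replicate 1. Fatty acid oxidation lost its call without that array (0.30) and without TTg replicate 2 (0.21) and was at 0.82 without TTg replicate 1. Glycolysis lost its call without Ctrl 2-month replicate 2 (0.29) or TTg replicate 1 (0.27). The mean of the factors was 1.16 without TTg replicate 1.

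Epicardial and mesothelial genes were lower in 13 of 13 (mean −0.99, adjusted p = 1.10e-05), and Gpm6a (−2.49 ± 0.48) passed adjusted over the list alone. Cell cycle genes were lower in 19 of 26 (mean −0.31, adjusted p = 0.00562), with Ube2c at −1.13 ± 0.50. Skeletal muscle genes were lower in 14 of 15 (mean −0.95, adjusted p = 0.00562). These 3 lists had an adjusted p = 0.631 with an estimated correlation. The skeletal muscle mean was 0.16 without Ctrl 2-month replicate 1, not past the threshold, and −2.06 without Ctrl 2-month replicate 2. Cell cycle lost its call without Ctrl 2-month replicate 1 (−0.26) or TTg replicate 2 (−0.23). In the atrial list, which did not pass (mean 0.74, adjusted p = 0.101), Bmp10, Tbx3 (1.48 ± 0.28) and 1 other gene passed adjusted over the list alone, and the list passed without Ctrl 2-month replicate 1 (0.63) or TTg replicate 2 (1.06). Among endothelial genes (mean −0.29, adjusted p = 0.201), Kdr (2.14 ± 0.33) and, in the lower direction, 2 others passed adjusted over the list alone. The endothelial list passed without Ctrl 2-month replicate 2 (−0.54). Antigen presentation (−0.52, adjusted p = 0.0611) passed in 8 of the 13 alternatives that kept the preset correlation. Sarcomere (0.34) and adipocyte genes (−1.45) passed without Ctrl 2-month replicate 2, and erythroid (−0.99) and circadian genes (−0.82) without TTg replicate 2. Y-linked genes passed in 4 of the 12 alternatives that kept the preset correlation, among them without Ctrl 2-month replicate 1 (−6.33). Median and mean differed in sign for B and plasma cells (0.10 and −0.08) and for neutrophils and mast cells (0.18 and −0.05), and camera's direction for T and NK cells was lower at a mean of 0.02, with no call (adjusted p = 0.944).

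Further named genes with high differences were Cwc22 (3.49 ± 1.12), Tmem94 (2.82 ± 0.57) and the transferrin receptor gene Tfrc (2.56 ± 0.56), and with low differences Rmrp (−4.61 ± 0.69), the retinaldehyde dehydrogenase gene Aldh1a1 (−3.40 ± 0.91), H2ac15 (−3.11 ± 0.94) and Omd (−3.06 ± 0.51). None passed, with adjusted p between 0.340 and 0.417. Cwc22 varied widely between the TTg arrays (SD 2.92), and its difference was 5.55 without TTg replicate 1.

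In limma 0 features passed, against 2156 at an unadjusted p under 0.05, 955 higher and 1201 lower. With an array left out, some features passed. Without Ctrl 2-month replicate 1 they included Y-linked genes, such as Eif2s3y (−8.02). Without Ctrl 2-month replicate 2 they included skeletal muscle and adipocyte genes, such as Myh2 (−7.09) and Adipoq (−6.12). These genes follow the values of the Ctrl 2-month array left in. Without TTg replicate 1 they were mostly Cwc22 (5.55) and unnamed chromosome 2 features numbered in sequence, several with the same difference of 5.40. Bmp10 passed without Ctrl 2-month replicate 1 (4.81) and without Ctrl 2-month replicate 2 (9.29), with an adjusted p from 0.00231 to 0.867 over its alternatives. Groups did not overlap for 40.07% of features, against 33.33% by chance. Of the 37 lists 16 passed with the preset correlation, 4 higher and 12 lower, and 9 passed without Ctrl 2-month replicate 1. With an estimated correlation or with fry's test for a change in 1 direction, 0 lists passed, and its test for changes in either direction passed mural cells (adjusted p = 0.0407) and B and plasma cells (adjusted p = 0.0464).

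The 3 comparisons share arrays, so they are not independent. Of the lists past the threshold, 9 were called both for TTg against Ctrl at 3 months and for Ctrl at 3 against 2 months, 8 of them in opposite directions. The lists lower in TTg and higher with time numbered 7, where independent calls would give 3.03, and 1 was higher in TTg and lower with time, where independent calls would give 0.405. Both comparisons use the Ctrl 3-month arrays with opposite signs, which yields opposed differences with no effect at all. Across features, the covariance of the 2 differences was −0.0887. Unchanged groups sharing those arrays gave −0.055 on average in 1000 simulated draws, a difference of −0.0337. The draws used each feature's spread after moderation across features, which pulls large spreads down. Such draws can give too weak a covariance, so the difference may come partly from this setting and was not taken as an effect. The covariance was −0.230 without Ctrl 3-month replicate 2 and −0.0497 without Ctrl 2-month replicate 2. The latter was closer to 0 than the simulated mean for all arrays, so the difference depends on single arrays. A lone Ctrl 3-month array would give a more negative covariance with no effect. No draws were made for that case, so −0.230 has no simulated value beside it. The correlation was −0.411, against −0.5 in the simulation. Of the 8 opposed lists, 3 also passed for TTg at 3 months against Ctrl at 2 months, namely other extracellular matrix, activated fibroblast genes and proteases, each lower in TTg. Immediate early genes had a mean of −0.06 there (camera, adjusted p = 0.444) and oxidative phosphorylation genes one of −0.01 (adjusted p = 0.676). For these lists TTg hearts lay near Ctrl hearts at 2 months, and the Ctrl 3-month pair stood apart. Whether the change over time differed between the genotypes was not tested, since TTg hearts at 2 months are not among the groups.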

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

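Of 5524 alternatives for single genes, 5443 kept their side of the threshold and either their direction or a change of sign smaller than the spread between replicates. Another 36 moved past the threshold, 14 moved out of it and 31 turned sign by more than that spread with no call. These alternatives belong to 370 gene results, of which only 2, Jchain and Adh1, were past the threshold with all arrays. The other results had no call to lose, so all 14 losses were alternatives of these 2. The 1440 alternatives for gene lists all kept the preset correlation, with directions as camera gives them. Of these, 1282 were unaltered in this sense, 89 moved past the threshold and 45 moved out. Another 18 turned by more than the spread with no call, and 6 reversed with a call before or after. Only 47 of the 111 list results were past the threshold with all arrays. Not counted here are the estimated correlation and fry's test for a change in 1 direction, under which every such list lost its call. A sign change was counted as a reversal only where the value passed the threshold with all arrays or in the alternative, a choice made after the results were seen. In all, the sign of the value turned in 45 gene alternatives with no call, and in 68 list alternatives besides the 6 reversed. Gata4 in TTg against Ctrl at 3 months was 1 of the genes, at 0.26 with all arrays and from −0.06 to 0.57 over the arrays left out, negative without Ctrl 3-month replicate 1 and without TTg replicate 1.

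With the correlation estimated for each list, and with fry's test for a change in 1 direction, 0 lists passed in each of the 3 comparisons, where the preset correlation gave 21, 10 and 16. Fry's test for changes in either direction passed 2, 5 and 2, with smallest adjusted p of 0.0133, 1.09e-04 and 0.0407. With an unadjusted p and a 2-fold minimum, 666 features passed in TTg against Ctrl at 3 months, 608 in Ctrl at 3 against 2 months and 877 in TTg against Ctrl at 2 months. In Ctrl at 3 against 2 months, where limma gave 1 feature, 0 passed with an intensity trend, with quantile normalization or without dim features, against 1776 at an unadjusted p under 0.05. In TTg against Ctrl at 2 months, where limma gave 0, 1 passed with the robust prior and 1 with features below 19 on every array, the alternative chosen after seeing the data. With only the 2 groups compared, 2 passed in TTg against Ctrl at 3 months. The causes of these differences were not tested.

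The replicate block, which treats equal replicate numbers as paired, gave 11 features in TTg against Ctrl at 3 months, 1 in Ctrl at 3 against 2 months and 5 in TTg against Ctrl at 2 months. The 11 were Jchain, Comp, Sfrp2, Ccn5, Mfap5, Meox1, Mmp3, Ccl9, Sfrp1, Frzb and Olfml3, all lower in TTg. The labels do not say whether replicates were paired. Correlations of replicate differences between groups were 0.133, 0.136 and 0.12.

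Over the 6 arrays left out in turn, features past the threshold ran from 0 to 2 in TTg against Ctrl at 3 months (0 without Ctrl 3-month replicate 2, TTg replicate 1 or TTg replicate 2), from 0 to 6 in Ctrl at 3 against 2 months (6 without Ctrl 2-month replicate 2) and from 0 to 22 in TTg against Ctrl at 2 months (22 without Ctrl 2-month replicate 2). Lists past the threshold ran from 14 to 24, from 7 to 16 and from 9 to 20. The covariance of the time and transgene changes ran from −0.230 without Ctrl 3-month replicate 2 to −0.0497 without Ctrl 2-month replicate 2. These fits hold fewer arrays. Where a Ctrl 2-month array was left out, passing features included Y-linked genes or skeletal muscle and adipocyte genes. These followed the values of the Ctrl 2-month array left in.

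Besides the sign changes with no call counted above, 6 list results reversed in camera's direction when an array was left out, with a call before or after. Skeletal muscle ran from −2.10 to 0.119 in Ctrl at 3 against 2 months and from −2.06 to 0.162 in TTg against Ctrl at 2 months, positive without Ctrl 2-month replicate 1. In Ctrl at 3 against 2 months, fatty acid oxidation ran from −0.380 to 0.439, macrophages from −0.456 to 0.557 and the cell cycle from −0.260 to 0.315, with their ends set by Ctrl 3-month replicates 1 and 2. For these 3 lists and the next, both ends were past the threshold, in opposite directions. The circadian clock in TTg against Ctrl at 3 months ran from −0.906 without TTg replicate 2 to 0.455 without TTg replicate 1.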

Other observations

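Among genes in chromosome order, 5 of 10 neighbours on chromosome 2 had values at least 2-fold higher in TTg than in Ctrl at 3 months at an unadjusted p under 0.01, and 0 of 1000 random gene orders held as many, with a highest count of 4. In TTg against Ctrl at 2 months 3 genes of that stretch met the same bounds, as many as in 160 of 1000 random orders. The 5 were Gm14403 (2.10 ± 0.41, n = 2), Gm6710 (1.76 ± 0.29), Zfp970 (1.60 ± 0.35), Gm14288 (1.23 ± 0.35) and Gm14434 (1.09 ± 0.24), none past the threshold over all features (adjusted p 0.646 to 0.661). They were chosen after their values were seen. In all, 270 features share identical values with another feature, so neighbours of similar sequence are not independent measurements.

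The tests for the 3 patterns below were chosen after the result was seen, except those of atrial genes outside the pattern, of right atrial tissue and of hearts without a Y chromosome, which were written before the genes they use were examined. A difference between the genotypes by design stays open, untested, for the fibroblast, matrix and macrophage lists and for Bmp10. It does not account for the Y-linked genes, which split the Ctrl pair at 2 months (Eif2s3y 2.48 and 10.86). For Myl4 and Sln, 3 of 4 Ctrl arrays lay near the level of the TTg arrays (Myl4 at 14.39, 15.09 and 16.08 against 16.23 and 14.53).

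Fibroblast, matrix and macrophage lists were lower in TTg than in Ctrl at 3 months. A lower share of all non-cardiomyocyte cells would lower endothelial and mural genes as well. The gap between activated fibroblast genes and these differed by −1.267 (SE 0.558, 2.27 SE), and the endothelial and mural genes differed by −0.10 (SE 0.129). With 3 residual degrees of freedom a gap of 2.27 SE is weak, and the activated list also defined the pattern, so this does not decide the question. The endothelial list alone passed at −0.46 without Ctrl 3-month replicate 2. A smaller share of scar tissue in the sampled heart may lower resting fibroblast genes too, and these differed by −0.745 (SE 0.439), which leaves the question undecided. A single array would have to carry the pattern alone, and leaving out 1 array ended the calls of 0 of the 6 lists, but these calls rest on the preset correlation and none passed with an estimated one. Without Ctrl 3-month replicate 1 the means stayed negative but shrank from −1.91 to −1.06 for late scar, −1.37 to −0.85 for activated fibroblast and −1.21 to −0.70 for macrophage genes, so that array may add to the size.

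Myl7, Myl4 and Sln were higher in TTg than in Ctrl at 3 months, and so was Bmp10. No atrial tissue in Ctrl 3-month replicate 2, alone low in Myl7, Myl4 and Sln, stays open, because 3 of 4 atrial muscle genes outside the pattern (Mybphl, Sbk2 and Sbk3, but not Kcnj3) were lowest in that array with a median gap over the 4 of 1.05, between the bounds written beforehand. It does not account for Bmp10, because the other Ctrl array, which held the 3 transcripts, had Bmp10 8.59 below the lower TTg array, at a value near the floor. Right atrial tissue in the TTg arrays alone would raise 4 other right atrial and sinus node genes, whose median difference was 0.147, within the bound written beforehand for no such tissue. The test was taken as undecided, a condition added after the values were seen, because Isl1 (3.19 to 3.58) and Vsnl1 (2.51 to 2.88) lay near the floor and the other 2 genes differed by 2.24 (Hamp) and 0.22 (Rgs6).

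Y-linked transcripts were low in 5 of 6 arrays of hearts labelled male. Probes that do not hybridise are an unlikely cause, since 3 of the 3 measured Y-linked genes lay above the median of all features in Ctrl 2-month replicate 2. RNA from hearts without a Y chromosome may be the cause, since 4 of 4 genes that escape X inactivation were lowest in that array, at 10.14 for Kdm6a, 13.93 for Eif2s3x, 7.15 for Kdm5c and 13.70 for Ddx3x. The gap for Ddx3x to the next array was small, with 13.81 there. Sex would then differ within the Ctrl 2-month pair, and the comparisons with that pair would partly mix sex with time. The comparison at 3 months would lie within 1 sex, but the Ctrl 2-month pair still enters the pooled spread behind its SE and p.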
